A study of Mus musculus with 6 samples.

How the data were processed

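RNA was extracted from sorted tumor cells and sequenced by a commercial provider, per the labels' protocols. The deposited table holds TPM values for 24493 genes in 6 libraries, made with Salmon against mm10 per the submitters' processing notes. TPM divides each transcript's estimated reads by its length and scales each library to the same total, so that very short genes such as Mir6236 can take a large share and lower all others. The Salmon version and transcript annotation are not given in the sources used here. Sequencing depth is unknown, so no counting interval could be given and precision rests on the spread between libraries. Groups and replicate numbers were taken from the sample titles.

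Genes with at least 1 TPM in at least 2 libraries were kept (13720) and tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend and 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes on this scale understate changes of genes with low TPM. A log2 change is the GAFCP mean minus the control mean, and "adjusted over the list alone" repeats the adjustment within 1 list. The test was tried on simulated data for this comparison over 13720 genes, where 60% of 50 genes changed 1.5-fold were recovered, 80% at 2-fold, 100% at 4-fold and 98% at 8-fold, with 5 false calls. Simulated data with no change gave 0 calls. The simulated libraries had independent noise for each gene and few changed genes, unlike the real ones. These rates may therefore not carry over to the real comparison.

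Before the data were examined 24 gene lists and 12 cell type marker lists were fixed, together with the rule for named genes. Lists with at least 5 tested genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and were adjusted over all lists tested. Camera was also run with the correlation estimated from the libraries and on ranks. A further alternative was fry, which asks whether a list changes without comparing it with other genes. With the estimated correlation, the type I interferon, MHC class II, macrophage, and T and NK cell lists stayed called. The mitochondrially encoded genes were not used here because the table holds 0 of the 13. B and plasma cell markers (2 tested) and skeletal muscle markers (4 tested) were given only as summed TPM. Summed TPM of each marker list was compared by a two-sided exact permutation test over all 15 arrangements.

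Named genes were, first, the 12 highest and 12 lowest by log2 change among called genes with a mean of at least 5 TPM and both GAFCP libraries outside the control range, leaving out predicted gene names. Second came up to 4 called members of each list with the smallest p, and last a fixed set of treatment targets, tumor genes and markers. The text gives these in part, and some items under the rule, with 1 gene list, are not reported here. Genes named outside the rule in the report are Jak2, Sdc1, Naaa, Mir6236, Rn45s, Hba-a1, Hba-a2, Retnlg, Mmp9, Ly6g, Camp, Ltf and Ngp. In the closing section they are Krt18, Cdh1, Ch25h and members of lists made later. All these genes were named after their values were seen, except that Krt18, Cdh1 and Ch25h were set by tests written before their values were seen. Positions are those of GENCODE M21 on GRCm38, the assembly also called mm10, matched by symbol for 226 of 227 genes looked up. The positions span whole genes.

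Alternatives changed the pseudocount (0.1 and 5), the filter, the scaling (median of ratios, quantile normalization, and rescaling without the 50 most abundant genes), the variance model, the threshold, library weights and the replicate number as a block, and left out each library in turn. Alternatives added after the data were seen used either pair of control libraries, averaged pairs of libraries to 3 units, or left out microRNA and small nucleolar RNA genes. Count-based tests were not used because the values are TPM.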

Results

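Bulk RNA sequencing was read from 6 libraries of mouse pancreatic tumor cells. The cells, of a single named tumor cell clone, had been sorted from tumors implanted under the skin of C57BL/6 mice. Of these libraries 4 came from control tumors and 2 from tumors given a combination called GAFCP in the labels, made of gemcitabine, abraxane, an agonist of CD40 and antibodies that block CTLA-4 and PD-1. Gemcitabine is a nucleoside analog that blocks DNA synthesis and abraxane is albumin-bound paclitaxel, which stabilizes microtubules. CD40 agonists activate antigen-presenting cells, and CTLA-4 and PD-1 are inhibitory receptors of T cells. The comparison asks how gene expression of the sorted tumor cells differed with the treatment. The deposited table gave TPM values (transcript abundance scaled to the same total in each library) for 24493 genes, and the sequencing depth of each library is unknown because TPM keeps no depth. The labels do not say whether libraries of a group came from separate animals or tumors. The p-values therefore measure only the spread between these libraries, which may be technical.

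The GAFCP libraries stood apart from the controls. The first principal component held 66.0% of the variance and placed the GAFCP libraries at 46.8 and 46.3 and the controls between -26.9 and -19.5. Pearson correlation across genes, which are not independent replicates, was 0.989 between the GAFCP libraries, 0.982 to 0.989 among controls and 0.945 to 0.954 between groups. The second component (13.8%) placed control libraries 1 and 2 at 13.8 and 20.8 and control libraries 3 and 4 at -20.3 and -18.1. With control libraries 1 and 2 alone 6602 genes passed the test, and with control libraries 3 and 4 alone 5424 passed, choices made after seeing the data. Mir6236, named as a microRNA gene, took between 7.59% and 11.2% of all TPM in each library. The ribosomal RNA precursor gene Rn45s was listed at 5332 TPM (GAFCP library 2) to 8989 TPM (control library 1). Whether the Mir6236 signal came from a microRNA or from ribosomal RNA was not examined.

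Of 13720 genes tested, 6515 differed between GAFCP and control libraries, 2606 of them higher and 3909 lower with GAFCP (40% higher). Among these, 644 were at least 2-fold higher and 344 at least 2-fold lower on the log2(TPM + 1) scale, and 164 and 57 reached 4-fold. Among the genes named by rule, Nos2, Gbp4 and Gbp10 had the largest increases, and Ttr and Tff1 were among the largest decreases. The groups did not overlap for 8458 genes, where chance gives 13.3% of those tested. With median-of-ratios scaling the split was 3449 higher and 3425 lower. Without GAFCP library 1 the count was 4258 and without GAFCP library 2 it was 4313, the remaining GAFCP library being assumed to vary as the controls did.

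The largest increase among genes named by rule was Nos2, the inducible nitric oxide synthase, on chromosome 11 from 78920787 to 78960254 (mm10). Nos2 was 4.15 ± 0.409 TPM (SD, n = 4) in controls and 144.4 ± 3.38 TPM (SD, n = 2) with GAFCP, a log2 change of 4.82 ± 0.08 (SE; limma adjusted p = 1.9e-08). Guanylate-binding proteins, GTPases that act against intracellular pathogens, were also among these genes, with log2 changes of 4.55 for Gbp4, 3.88 for Gbp10, 3.56 for Gbp5 and 3.50 for Gbp2. Gbp2 (chromosome 3, 142620602 to 142638008) went from 97.3 ± 3.58 to 1110 ± 10.4 TPM (SD). Saa3, an acute-phase protein, rose by 3.75, Ubd, a ubiquitin-like modifier, by 3.56, and Apol6 by 3.48. Ido1, which degrades tryptophan, rose from 15.9 ± 1.23 to 197.1 ± 5.32 TPM (SD; chromosome 8, 24584136 to 24597009). The Gbp genes form a family of related genes, and how reads were divided among its members was not examined here. Snord42a also entered the list (log2 change 3.50 ± 0.91, SE), with an adjusted p of 0.108 without GAFCP library 1 and 0.0821 with a robust variance model.

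The largest decrease among genes named by rule was Ttr, the thyroid hormone carrier transthyretin, on chromosome 18 from 20665280 to 20674321. Ttr went from 34.8 ± 4.51 TPM (SD, n = 4) to 0.532 ± 0.312 TPM (SD, n = 2), a log2 change of -4.55 ± 0.15 (SE; limma adjusted p = 2.3e-07). Tff1 and Tff2, which encode trefoil peptides of gastrointestinal mucus, had log2 changes of -3.41 and -3.27. Dmbt1, a mucosal scavenger glycoprotein, fell from 116.3 ± 7.28 to 12.7 ± 0.373 TPM (SD; chromosome 7, 131032053 to 131121630). Gc, the vitamin D-binding protein, changed by -3.38, the mast cell protease gene Mcpt4 by -3.09, the gap junction gene Gjb1 by -2.96 and the aldo-keto reductase Akr1c19 by -2.95. Prlh was listed at 0 in both GAFCP libraries and averaged 16.6 TPM in controls. The short microRNA genes Mir7237, Mir680-2 and Mir5119 had log2 changes of -3.09, -2.90 and -2.87. Mir7237 did not pass without GAFCP library 1 (adjusted p = 0.157), without control library 3 (adjusted p = 0.0502) or with a robust variance model (adjusted p = 0.0981).

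Interferon-response genes rose almost throughout. All 34 tested genes of the type I interferon list were higher (34 also adjusted over the list alone), with a median log2 change of 1.74 (camera adjusted p = 1.4e-25, and adjusted p = 0.0345 with an estimated correlation). Bst2, which tethers viruses to the cell surface, rose from 357.5 to 1219 TPM, and Irf7, Oasl2 and Xaf1 rose by 2.40, 2.30 and 2.21 on the log2 scale. Of 30 interferon gamma-induced genes 29 were higher (29 adjusted over the list alone) and Jak2 did not pass, with a median of 2.24 (camera adjusted p = 4.3e-28, and adjusted p = 0.128 with an estimated correlation). Cxcl9, a chemokine that draws T cells, rose from 34.6 ± 0.802 to 283.9 ± 5.44 TPM (SD), and the GTPase genes Iigp1 and Tgtp1 rose by 3.38 and 3.12.

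Antigen presentation genes rose in the same libraries. Of 22 MHC class I genes 20 were higher (20 adjusted over the list alone), with a median log2 change of 1.46 (camera adjusted p = 3.3e-17, and adjusted p = 0.132 with an estimated correlation). B2m, the class I light chain on chromosome 2 from 122147686 to 122153083, went from 2108 ± 40.7 to 5698 ± 37.2 TPM (SD). H2-K1 went from 1857 ± 37.5 to 5032 ± 36.7 TPM (SD), H2-T23 rose by 1.76, and the immunoproteasome subunit Psmb9 by 2.03. All 9 tested MHC class II genes were higher (9 adjusted over the list alone), with a median of 2.44 (camera adjusted p = 9.7e-12, and adjusted p = 0.031 with an estimated correlation). Cd74, the class II invariant chain, went from 171.0 ± 2.24 to 1581 ± 18.7 TPM (SD; chromosome 18, 60803848 to 60812652), and H2-Aa, H2-Eb1 and H2-Ab1 rose by 3.53, 3.52 and 3.29. Pan-leukocyte markers (median 1.26) and macrophage markers (median 1.64) were higher in the same libraries as these genes and the interferon-response genes.

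Markers of immune cells were higher in the GAFCP libraries even though the labels describe sorted tumor cells. The marker or gate used for the sort is not given in the sources used here. All 21 macrophage and monocyte markers were higher (21 adjusted over the list alone; median log2 change 1.64, camera adjusted p = 7.1e-19, and adjusted p = 0.031 with an estimated correlation), and their summed TPM went from 1656 ± 48.6 (SD, n = 4) to 6300 ± 44.3 (SD, n = 2). Apoe, a lipid carrier, went from 557.2 to 2780 TPM, the lysozyme gene Lyz2 from 411.6 to 1357 TPM and the complement gene C1qa from 102.6 to 447.9 TPM. All 10 pan-leukocyte markers were higher (10 adjusted over the list alone; median 1.26, camera adjusted p = 2.0e-08, and adjusted p = 0.137 with an estimated correlation), among them Ptprc, which encodes CD45, from 2.73 ± 0.389 to 9.79 ± 0.479 TPM (SD). Of 15 T and NK cell markers 14 were higher (14 adjusted over the list alone; median 1.28, camera adjusted p = 3.4e-08, and adjusted p = 0.0345 with an estimated correlation), at low levels such as 0.366 and 3.39 TPM for Cd3e. Of 9 neutrophil markers 7 were higher (7 adjusted over the list alone; median 1.45, camera adjusted p = 1.7e-04, and adjusted p = 0.0985 with an estimated correlation), S100a8 rising by 2.03. The others tested were Retnlg, averaging 2.63 TPM in controls and 1.77 TPM with GAFCP, and Mmp9, averaging 10.1 and 10.7 TPM. The neutrophil markers Ly6g, Camp, Ltf and Ngp stayed under 1 TPM in every library and were not tested. Of 16 fibroblast and pericyte markers 10 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.64, camera adjusted p = 2.1e-04, and adjusted p = 0.288 with an estimated correlation).

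Of the other marker lists tested, 1 was called. Of 7 erythroid and platelet markers 4 were higher (5 adjusted over the list alone; camera adjusted p = 0.0295, and adjusted p = 0.293 with an estimated correlation), among them the platelet factor gene Pf4, which rose by 1.21. This call was lost without control library 3 (adjusted p = 0.0618) and without GAFCP library 2 (adjusted p = 0.0974). It was also lost with median-of-ratios scaling (adjusted p = 0.069), with no filter (adjusted p = 0.0536) and at a mean of at least 5 TPM (adjusted p = 0.1). The globin genes Hba-a1 and Hba-a2 of this list moved in opposite directions. Hba-a1 averaged 65.9 TPM in controls and was 0 and 59.2 TPM in GAFCP libraries 1 and 2. Hba-a2 averaged 9.05 TPM in controls and was 78.4 and 28.2 TPM there. How reads were divided between these related genes was not examined. The dendritic cell, endothelial, adipocyte and keratinocyte lists were not called, with camera adjusted p of 0.501, 0.942, 0.165 and 0.865. The endothelial median was -0.11 where its test pointed up. The adipocyte list (median -0.81) was called with control libraries 1 and 2 alone (median -1.25, adjusted p = 0.0419), a choice made after seeing the data. Its summed TPM was 22.8 and 14.2 in control libraries 1 and 2, 7.23 and 8.49 in control libraries 3 and 4, and 4.96 and 4.39 with GAFCP. They held 2 higher and 1 lower, 3 and 3, 0 and 2, and 1 and 1 genes past the test, the same counts adjusted over the list alone. Summed TPM of the B and plasma cell markers, 99.2% of it from Sdc1, was 411.7 ± 11.5 (SD) in controls and 390.5 ± 7.73 (SD) with GAFCP, and that of the skeletal muscle markers was 63.2 ± 5.87 and 55.0 ± 4.81. With the mean of log2 values the B and plasma cell difference turned from -0.08 to 0.40 (exact p = 0.0667) and the skeletal muscle difference from -0.20 to 0.15 (exact p = 0.267). Jchain, an immunoglobulin joining chain, rose from 0.905 to 4.37 TPM (adjusted p = 1.4e-04). An exact permutation test over the 15 arrangements gave p = 0.0667, the smallest this design allows, for the pan-leukocyte, T and NK cell, macrophage, neutrophil, dendritic cell, fibroblast and erythroid sums (two-sided, 12 sums tested, adjusted p = 0.114). Naaa made up 62.5% of the dendritic cell sum and Pf4 36.8% of the erythroid and platelet sum. With the mean of log2 values in place of the sum, the dendritic cell difference went from 0.26 to 0.08 (exact p = 0.2) and the erythroid and platelet difference from 0.62 to 0.19 (exact p = 0.333).

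**Figure D1:**
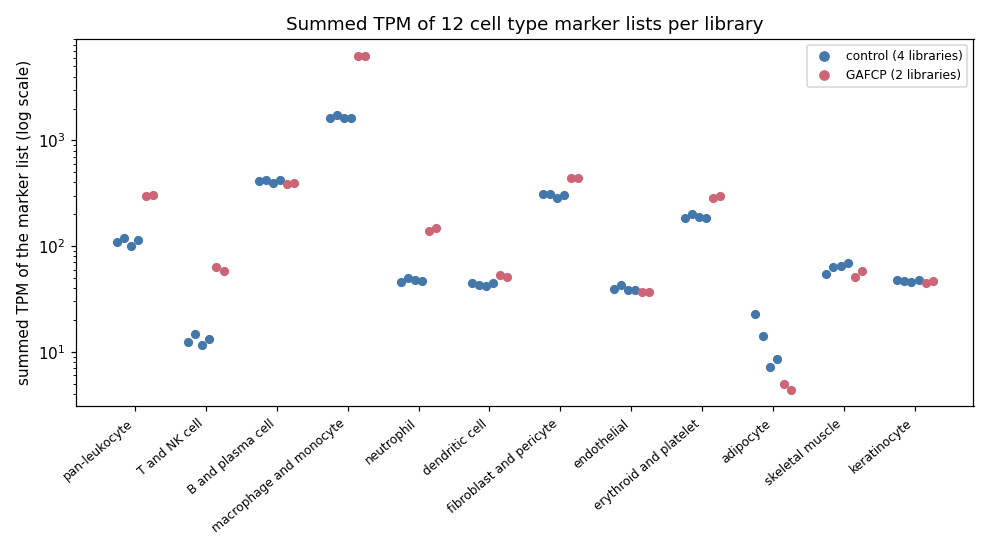
Summed TPM of each cell type marker list (log scale) in the 4 control libraries (blue) and the 2 GAFCP libraries (red), each point being 1 library. The macrophage sum averaged 1656 TPM in controls and 6300 TPM with GAFCP, while the keratinocyte sums of the groups overlapped.

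Checkpoint ligands, chemokines and inflammatory targets also rose, in libraries where the leukocyte markers were higher (median 1.26). Of 21 checkpoint and costimulatory genes 13 were higher and 5 lower (13 and 5 adjusted over the list alone; median 0.89, camera adjusted p = 8.2e-04, and adjusted p = 0.137 with an estimated correlation). Cd274, which encodes PD-L1, went from 7.65 ± 0.771 to 53.8 ± 2.07 TPM (SD; chromosome 19, 29367455 to 29388095), the death receptor gene Fas rose by 1.61, Vsir by 1.35 and the ectonucleotidase Nt5e by 0.96. Cd40, the target of the agonist, averaged 0.636 TPM in controls and 2.78 TPM with GAFCP (adjusted p = 0.0024), and Pdcd1 and Ctla4, the targets of the blocking antibodies, averaged 0.413 and 0.427 TPM in controls and 1.59 and 1.31 TPM with GAFCP. Of 28 myeloid-recruiting chemokines and cytokines 18 were higher and 4 lower (19 and 5 adjusted over the list alone; median 0.75, camera adjusted p = 8.7e-09, and adjusted p = 0.132 with an estimated correlation). Cxcl1, a neutrophil chemokine, went from 58.9 ± 3.40 to 228.1 ± 0.0568 TPM (SD), Ccl7 rose by 1.94, Cxcl5 by 1.27 and the prostaglandin synthase Ptgs2 by 2.08. Csf1, the macrophage growth factor, had a log2 change of -0.19 and did not pass (adjusted p = 0.065), though it did without control library 3 (adjusted p = 0.0379), with rescaling without the 50 most abundant genes (adjusted p = 0.0379) and with library weights (adjusted p = 0.0281). Of 22 NF-kappaB targets 16 were higher (16 adjusted over the list alone; median 0.40, camera adjusted p = 3.4e-08, and adjusted p = 0.164 with an estimated correlation), with Nfkbia up by 1.45 and Icam1 by 1.13. Of 26 immediate-early genes, which also respond to tissue dissociation, 20 were higher and 3 lower (20 and 3 adjusted over the list alone; median 0.65, camera adjusted p = 1.3e-10, and adjusted p = 0.137 with an estimated correlation), Atf3 rising by 2.48 and Fosb by 1.86.

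Cholesterol biosynthesis genes fell together. All 23 were lower with GAFCP (23 adjusted over the list alone), with a median log2 change of -0.82 (camera adjusted p = 9.9e-12, and adjusted p = 0.135 with an estimated correlation). Cyp51, a sterol demethylase, went from 62.4 ± 2.89 to 21.1 ± 1.11 TPM (SD; chromosome 5, 4081145 to 4104746). The sterol pathway enzymes Idi1 and Msmo1 changed by -1.38 and -1.15. Macrophage (median 1.64), pan-leukocyte (1.26) and fibroblast (0.64) markers were higher in these libraries.

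Epithelial genes were mostly lower. Of 30 epithelial and ductal identity genes 19 were lower and 5 higher (19 and 5 adjusted over the list alone), with a median log2 change of -0.56 (camera adjusted p = 2.3e-04, and adjusted p = 0.405 with an estimated correlation). Epcam, an epithelial adhesion molecule, went from 12.8 ± 0.239 to 1.54 ± 0.208 TPM (SD; chromosome 17, 87635979 to 87651129). The keratins Krt19 and Krt8 remained abundant while changing by -0.66 and -0.59, Krt19 from 1615 ± 33.1 to 1020 ± 14.6 TPM (SD), and Spint2 changed by -0.61. The epithelial-mesenchymal transition list was not called (11 higher, 7 lower of 25; 11 and 8 adjusted over the list alone; camera adjusted p = 0.0543), though the activin subunit gene Inhba rose by 2.36 and the integrin gene Itga5 by 0.91. This list was called without control library 2 (adjusted p = 0.0494) and without GAFCP library 2 (adjusted p = 0.04). It was also called at a mean of at least 5 TPM (adjusted p = 0.0256), with median-of-ratios scaling (adjusted p = 0.044) and without cell type marker genes (adjusted p = 0.0441). Vim rose by 0.18. In the same libraries the pan-leukocyte (median 1.26), macrophage (1.64) and fibroblast (0.64) markers were higher.

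Genes of energy metabolism and translation shifted by small amounts. Of 32 hypoxia and glycolysis genes 24 were higher and 1 lower (24 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 2.5e-09, and adjusted p = 0.293 with an estimated correlation), with the glucose transporter Slc2a1 up by 0.91, the lactate transporter Slc16a3 by 0.83 and Bnip3 by 0.84. Of 58 oxidative phosphorylation genes 34 were lower and 2 higher (36 and 2 adjusted over the list alone; median -0.16, camera adjusted p = 5.1e-05, and adjusted p = 0.406 with an estimated correlation), Ndufa4 changing by -1.06. Of 76 cytosolic ribosomal protein genes 49 were lower and 4 higher (52 and 4 adjusted over the list alone; median -0.15, camera adjusted p = 1.7e-05, and adjusted p = 0.632 with an estimated correlation). The median over all tested genes was -0.07. These changes stood beside higher macrophage (median 1.64), pan-leukocyte (1.26) and fibroblast (0.64) markers.

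Genes tied to the cytotoxic drugs were compared in libraries that also had higher pan-leukocyte (median 1.26) and macrophage (1.64) markers. Of 40 S phase and replication genes 25 were higher and 1 lower (27 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 2.2e-08, and adjusted p = 0.158 with an estimated correlation), including Ccne1 by 0.82, Cdc45 by 0.78 and Rrm2 by 0.64. Of 36 G2/M genes 11 were higher and 6 lower (11 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.0101, and adjusted p = 0.566 with an estimated correlation), with Top2a up by 0.86 and Ccnb2 changing by -0.57. Mki67, a proliferation marker, had a log2 change of 0.21 (adjusted p = 0.107). It passed with median-of-ratios scaling (adjusted p = 0.0153), quantile normalization (adjusted p = 0.0141) and without control library 3 (adjusted p = 0.0341). Of 21 genes of gemcitabine transport and metabolism 8 were higher and 3 lower (8 and 3 adjusted over the list alone; median 0.02, mean 0.28, camera adjusted p = 0.0369, and adjusted p = 0.545 with an estimated correlation), led by the nucleoside transporter Slc28a2 (2.29) and the nucleotide hydrolase Samhd1 (1.80). Under quantile normalization the median of this list changed sign (-0.04) and its call was lost (adjusted p = 0.122). The call was also lost with rescaling without the 50 most abundant genes (median -0.01, adjusted p = 0.0622), at a mean of at least 5 TPM (adjusted p = 0.0545) and with ranks (adjusted p = 0.0593). Of 28 unfolded protein and integrated stress response genes 10 were higher and 4 lower (10 and 4 adjusted over the list alone; median 0.13, camera adjusted p = 0.0057, and adjusted p = 0.541 with an estimated correlation). The neuronal-type tubulin Tubb3 rose by 1.55 in a tubulin list that was not called (7 higher, 5 lower of 22, likewise adjusted over the list alone; camera adjusted p = 0.156).

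Lists of p53 targets, DNA repair and apoptosis genes were not called, with camera adjusted p of 0.0944, 0.232 and 0.305. Of 27 p53 targets 10 were higher and 5 lower, in the same numbers adjusted over the list alone, with the cell cycle inhibitor Cdkn1a going from 25.9 ± 2.40 to 93.5 ± 1.37 TPM (SD) and Pmaip1 rising by 1.45, while Perp changed by -1.10. Of 33 DNA repair genes 6 were higher and 6 lower (3 and 4 adjusted over the list alone), and of 23 apoptosis genes 9 were higher and 9 lower, as adjusted over the list alone. Trp53 changed by -0.13 (adjusted p = 0.016) and did not pass without GAFCP library 1 (adjusted p = 0.0893), GAFCP library 2 (adjusted p = 0.118) or control library 4 (adjusted p = 0.0534), nor with median-of-ratios scaling (adjusted p = 0.151) or without the variance trend (adjusted p = 0.0585).

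**Figure D2:**
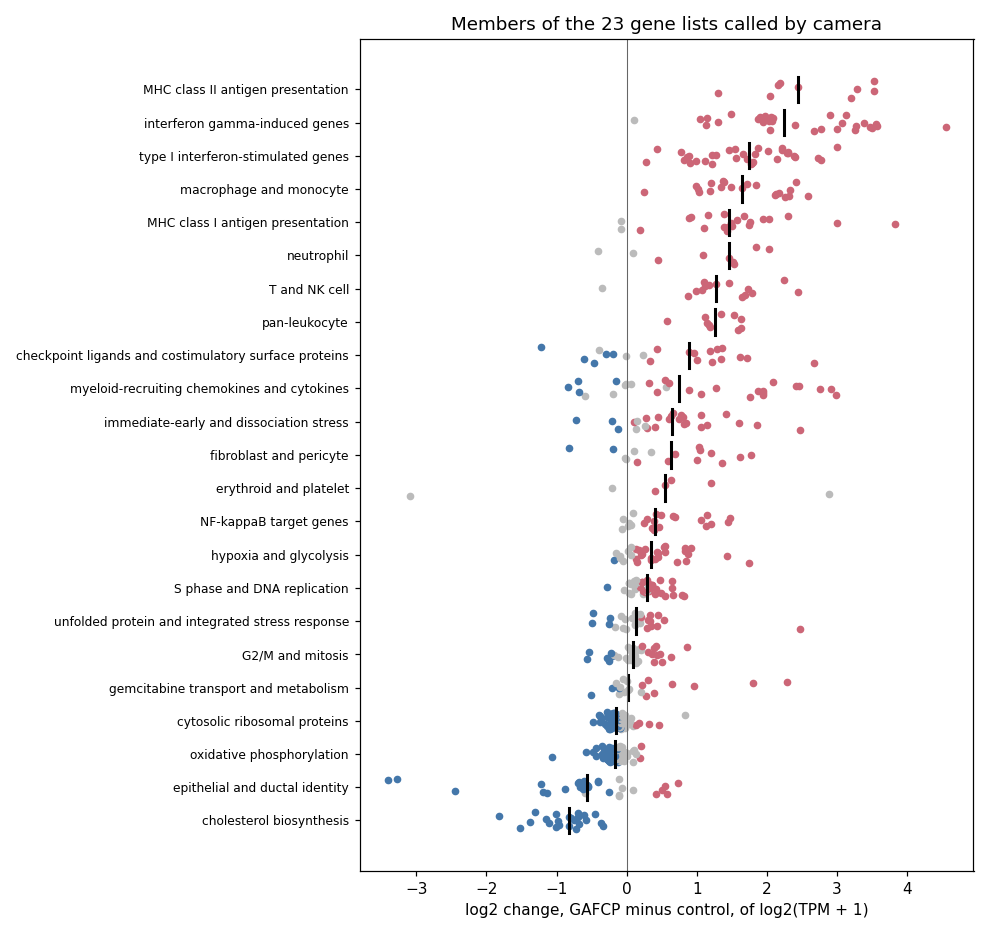
Log2 change (GAFCP minus control, log2(TPM + 1)) of each tested member of the 23 lists called by camera, with red and blue points for genes called higher and lower, grey for genes not called, and a bar at the median. Cholesterol biosynthesis has the lowest median (-0.82) and MHC class II the highest (2.44).

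**Figure D3:**
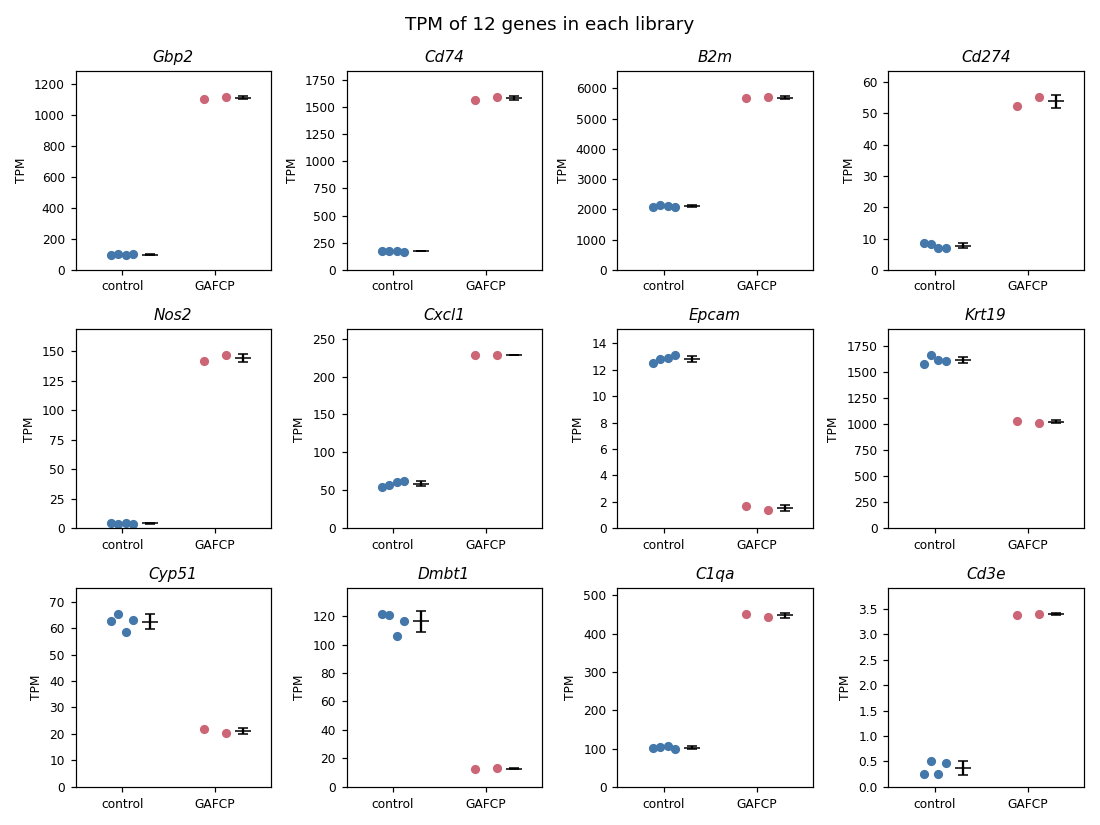
TPM of 12 genes in each control (blue, n = 4) and GAFCP (red, n = 2) library, with the mean and SD in black and each axis starting at 0. Gbp2, Cd74, B2m and Cd274 lie above the controls in both GAFCP libraries, and Epcam, Krt19, Cyp51 and Dmbt1 lie below.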

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

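Of the tests below, the count over other splits of the libraries was chosen after the result was seen. So were the comparison of the cholesterol list with epithelial transcripts and the test of a shift to a basal-like program. The oxysterol test was written before Ch25h was seen, but its LXR target list was made after the data were seen. Among 164 sets of 4 control values (named genes and marker sums), 8 had a library far from the other 3, where chance flags about 1 in 20, or 8.2. The gap to the nearest library, as a share of the range, was 0.846 for Irf7, 0.831 for Ccne1, 0.899 for Mki67 and 1 for Snord42a, each in control library 3. In control library 2 it was 0.879 for Tgtp1, 0.846 for Lyz2 and 0.873 for Pdcd1, and in control library 1 it was 0.838 for Cldn5. Mki67 was 12.9 TPM in control library 3 against a median of 16.1 TPM in the others, and Snord42a was 7.94 TPM there and listed at 0 in the others.

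Interferon gamma-induced and MHC genes were higher in the GAFCP libraries. Scaling was argued against, since the median log2 change of the interferon gamma list stayed between 2.26 and 2.30 under 3 other scalings. Immune cells among the sorted cells remain a candidate source. The pan-leukocyte median was 1.26, above 0.5 of the interferon gamma median, and all 10 markers lay above the control range in both GAFCP libraries. That share was a bar set beforehand and does not measure how much of the rise such cells could supply. The pan-leukocyte median and the macrophage median (1.64) both lay below the interferon gamma median of 2.24. Macrophage transcripts were abundant, with Apoe at 2780 TPM and C1qa at 447.9 TPM, although the labels describe sorted tumor cells. The marker or gate of the sort is not given in the sources used here. How much of the rise arose in tumor cells, with treatment as an untested biological explanation, stays open.

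Epithelial and ductal identity genes were lower. Dilution of tumor cells by other cells would lower abundant epithelial transcripts by about the same factor as Epcam, which changed by -2.45. The median change of Krt8, Krt18, Krt19 and Cdh1 was -0.35, which argues against dilution as the whole cause of a fall of that size. These 4 split into Krt18 (-0.06) and Cdh1 (-0.10) against Krt8 (-0.59) and Krt19 (-0.66), the latter close to the median of the epithelial list (-0.56). Dilution lowers all transcripts of the diluted cells alike. The changes of Krt18 and Cdh1 therefore leave room for dilution as only a small part of the fall, unless both rose within the tumor cells. That part, and a change within the tumor cells with treatment, stay open.

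Cholesterol biosynthesis genes were lower. Their median lay -0.47 from the median change of Krt8, Krt18, Krt19 and Cdh1 (-0.35), beyond the SD of those 4 changes (0.315), which argues against dilution of tumor cells as the whole cause. The distance was -0.75 and -0.71 from Krt18 and Cdh1 and -0.23 and -0.15 from Krt8 and Krt19. Krt18 (-0.06) and Cdh1 (-0.10) leave room for dilution as only a small part of the fall, unless both rose within the tumor cells. A rise of oxysterols acting through LXR was tested as a hypothesis: Ch25h, which makes an oxysterol, was lower (-0.46), against that explanation in the form tested, while 50% of the tested LXR target genes were higher. Other routes to lower sterol synthesis, treatment among them, stay open.

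The 6515 genes called between GAFCP and control libraries were set beside all 15 splits of the 6 libraries into 4 and 2, of which only 1, the real one, called as many. The highest of the other splits called 62. Each of the other splits put at least 1 GAFCP library in the group of 4, which added the group difference to the spread. Their low counts therefore do not measure what chance would give. With 15 splits a share under 0.05 cannot be reached.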

How the results depend on the processing

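Settings using pairs of controls, averaged units or no small RNA genes were added after the data were seen. Across all settings, the genes called in both a setting and the reported test had the same direction. The count of 6515 genes ranged from 4258 to 7226 (higher 1715 to 2610, lower 2514 to 4641) when each library was left out, with fewer samples. A 2-fold minimum left 988 genes, 644 higher and 344 lower, by construction. Other settings gave 5367 to 7605 genes. The 17 gene lists and 6 cell type lists called fell to 2 and 2 with an estimated correlation, and at a mean of at least 5 TPM, with fewer genes tested, to 17 and 3. With fry the G2/M list was not called (adjusted p = 0.069), and the p53, tubulin, epithelial-mesenchymal and adipocyte lists were (0.0144, 0.0438, 0.0103 and 0.0197). Because fry makes no comparison with other genes, and 47.5% of all tested genes were called, these calls do not show that the lists changed more than other genes. Marker sums changed sign in 3 cases: with the mean of log2 values B and plasma cells moved to 0.40 and skeletal muscle to 0.15, and the keratinocyte sum ranged from -0.077 to 0.0042 on leaving out a library (the cause was not tested). With the replicate number as a block, which left 1 residual degree of freedom, 5894 genes were called, and so was the adipocyte list (median -1.25, adjusted p = 0.0378). In that setting 8 genes named by rule lost their call. Among them were Vim (limma adjusted p = 0.0523), Pdcd1 (0.147), Ctla4 (0.0518), Trp53 (0.0519), Mir5119 (0.0651) and Mir7237 (0.170). The number is shared, but the labels say nothing of pairing. Correlations of deviations from the group mean were -0.0073 for GAFCP 1 with control 1 and -0.0195 for GAFCP 2 with control 2. The deviations of the 2 GAFCP libraries mirror each other, so these values cannot decide whether libraries were paired. Depth is unknown, so what it limits could not be assessed.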

Other observations

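The lists in this part were made after the data were seen, and the classical, basal-like and complement lists after some of their members had been seen. Genes of the classical subtype of pancreatic cancer, a gastrointestinal-type program, were lower in the GAFCP libraries. Of 24 tested, 21 were lower and 0 higher, with a median log2 change of -0.76 (camera adjusted p = 7.6e-10 over 5 added lists, and adjusted p = 0.261 with an estimated correlation). Part of this list was picked with knowledge of the result, because 7 of its tested members had been seen to change. Over the 17 tested genes not seen before, 14 were lower, with a median of -0.68 (camera adjusted p = 4.7e-06 at the preset correlation). These 17 were chosen after related genes had been seen lower, so they are not independent support. They were not tested with an estimated correlation. The protease gene Ctse went from 352.9 to 127.3 TPM, the iron exporter Slc40a1 from 47.2 to 14.0 TPM, and the transcription factors Hnf4a and Pdx1 changed by -0.78 and -0.92. Smaller changes were seen for the transcription factors Gata6 (-0.36) and Foxa2 (-0.12), the latter not passing (limma adjusted p = 0.101). Agr2 was listed at 0 in both GAFCP libraries and averaged only 1.67 TPM in controls. Pan-leukocyte (median 1.26), macrophage (1.64) and fibroblast (0.64) markers were higher in these libraries. The keratins Krt8 and Krt19 changed by -0.59 and -0.66, close to the median of this list, while Krt18 and Cdh1 changed by only -0.06 and -0.10.

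A shift from this classical program to a basal-like one was tested as a hypothesis. The basal-like list had a median log2 change of 0.21 (camera adjusted p = 0.242, and adjusted p = 0.644 with an estimated correlation), with 7 of 18 genes higher and 6 lower, so a gain of that program was not shown. Over its 13 tested genes not seen before the median was 0.13 (camera adjusted p = 0.59). Hmga2 rose by 0.90 while Lamb3 changed by -1.27.

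Complement genes were higher, in libraries where macrophage markers were also higher (median 1.64). Of 11 tested, 10 were higher and 1 lower (median 1.09, camera adjusted p = 5.9e-08, and adjusted p = 0.261 with an estimated correlation). Over the 9 tested genes not seen before, 8 were higher and 1 lower (median 0.87, camera adjusted p = 8.2e-06 at the preset correlation). These 9 were likewise chosen after related genes had been seen higher and were not tested with an estimated correlation. C4b went from 13.5 to 68.3 TPM and Cfb from 150.8 to 322.9 TPM, while C3 changed by -0.21. Fatty acid synthesis genes were lower alongside the cholesterol genes, 9 of 12 lower and 0 higher (median -0.51, camera adjusted p = 5.3e-04, and adjusted p = 0.425 with an estimated correlation), with Scd2 going from 313.7 to 152.0 TPM. The LXR target list was not called (5 higher, 3 lower of 10; camera adjusted p = 0.240, and adjusted p = 0.462 with an estimated correlation). Abca1 rose by 1.47 and Pltp by 2.59, both of which macrophages also express, and Srebf1 changed by -0.17.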
